A study of Homo sapiens with 24 samples.

How the data were processed

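RNA was sequenced from areas of airway tissue cut out by laser microdissection, in which stained sections are cut under a microscope so that chosen cells are collected alone. Per the labels' protocols, sections were 7 micron thick and an area of 800000 to 1200000 square micron was taken from each lesion. The 24 libraries came from 4 patients with lung squamous cell carcinoma. They comprised 7 of normal airway basal cells, 7 of premalignant airway lesions and 10 of tumor, and every patient contributed each stage. cDNA of patients 1 and 2 was made with the Ovation RNA-Seq System and selected for size on a gel. cDNA of patients 3 and 4 was made with version 2 of that kit and sheared by ultrasound, and the microscope also differed between patients. The kit was therefore shared by all stages of a patient and differed only between patients.

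The authors deposited a table of whole-number read counts per Ensembl gene and a table of RPKM, read counts scaled to gene length and library total, each with 1 column per library. The submitters' processing notes name the hg19 genome build, CASAVA 1.6.0, Bowtie 0.12.7 and bedtools, without saying which step each served. The annotation release, the treatment of reads that map to several genes and the use of strand are not given in the sources used here. In the deposited RPKM values the ratio of count to RPKM was a gene term times a library term, with a largest deviation of 9.9e-14 on the natural log scale, so both tables hold the same reads. No gene had a count above 0 with an RPKM of 0 or the reverse. The number of columns of per-sample values left unused was 0.

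The count table listed 55841 gene IDs, of which 38944 were paired with a symbol through a table of gene names and GENCODE release 29. Rows of the Y chromosome, XIST and TSIX, 463 in all, were left out of every analysis, and no coordinates are given because no annotation of the build used by the submitters was used here. Of 668 members of 30 gene lists, 658 matched a row, with older symbols translated where only 1 current symbol fitted. Gene lists, the main tests, the rule for named genes and the alternatives were set before the data were examined, apart from the fits named below as added and the later tests of explanations. By that rule the text names, per comparison, the 8 largest rises and the 8 largest falls among called protein-coding genes with a mean of at least 5 CPM (counts scaled to the library total) in 1 of the stages compared and the same direction in 4 of 4 patients. It also names up to 3 called members of each list with the smallest p and the same direction in 4 of 4 patients, and 18 fixed genes of airway epithelium and lung squamous cell carcinoma whether called or not, of which 1 is not reported here. The rule gave 48 distinct genes, and a gene outside it is said to be chosen after its values were seen.

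Total counts per library ranged from 644064 to 19567595. Libraries of the first kit held 644064 to 2433528 counts and those of the second kit 4295845 to 19567595. Where a group had 0 reads of a gene, a fold was computed against a floor of 3 reads over the group and given as a lower bound. Where a group had 1 to 3 reads, the ratio was given with a 95% interval. Such bounds and intervals cover counting error only, because amplified reads are not independent molecules.

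Areas of the same stage and patient are not independent, so their counts were summed, which gave 12 sums of 4 patients by 3 stages. No pair of libraries of the same stage and patient agreed within counting noise. Correlations of log2 CPM across genes between such areas, each over the pair's own set of 8502 to 18628 genes, ran from −0.103 to 0.846. They were −0.0604 to 0.0251 in normal areas of patient 1 and 0.217 in those of patient 4. In tumor they were 0.498 in patient 1, 0.124 in patient 2 and 0.697 to 0.846 in patients 3 and 4. Genes were kept by the filterByExpr function of edgeR 4.0.16 with stages as groups (at least 10 counts at the median depth in a sufficient number of sums, and at least 15 in total), which left 20246 genes. Sums were scaled by TMM factors of 0.731 to 1.25. The quasi-likelihood F test of edgeR was fitted to all 12 sums with the patient as a block, which left 6 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common dispersion was 1.58, so a typical gene varied between sums by more than its own mean. Levels are given as TMM-scaled CPM with the SD over 4 patients, and per-patient differences are of log2 CPM with a prior count of 2. Stages were compared pairwise, and the premalignant lesions were also tested against the midpoint of normal and tumor. The effect of the kit on the stage differences was tested as an interaction. The patients pair the sums: deviations of sums of the same patient from their stage means had a correlation across genes of 0.130 to 0.490, with a median of 0.349 over 12 pairs.

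Gene lists were tested with camera with a preset correlation between genes of 0.01, with an estimated correlation, and with fry, and p-values were adjusted over 87 tests of 29 lists in 3 comparisons. The list of cancer-testis antigens had under 3 tested members and was not tested. Members called were counted over all genes tested and, for each list, adjusted over the list alone. The tests were tried on simulated counts drawn from the observed means, library sizes and dispersions, with 200 genes changed by known folds. The edgeR test then called 0 to 1 unchanged genes per comparison. Of the genes changed between tumor and normal it called 2.38% at a 4-fold change, 8.89% at 16-fold, 29.5% at 64-fold and 60.5% at 256-fold. DESeq2 called 48 to 169 unchanged genes per comparison on the same simulated counts and is given as an alternative.

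Alternatives comprised DESeq2 1.42.0, other scaling factors, other filters, no patient block, the 24 libraries as samples, limma 3.58.1 on mean log2 CPM and on log2(RPKM + 1) or log2(RPKM + 0.1), libraries thinned at random to the total of the shallowest (seed 11), only the stages compared, each kit alone, and each patient left out in turn. A fit without the second premalignant library of patient 2 and a fit with the number of genes detected as a covariate were added after seeing the data. R 4.3.3, Python with pandas 2.3.3 and matplotlib 3.10.9 were used.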

Results

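Gene expression was measured by RNA sequencing in microdissected airway tissue of 4 patients with lung squamous cell carcinoma, a lung cancer whose cells show features of stratified squamous epithelium. The 24 libraries comprised 7 of normal airway basal cells, 7 of premalignant airway lesions and 10 of tumor. Several areas of a stage were taken in most patients, and they were summed so that n = 4 patients per stage. Total counts ranged from 696098 to 18892997 in normal libraries, from 644064 to 19567595 in premalignant libraries and from 1035905 to 18508865 in tumor libraries. The number of genes with at least 1 read differed with the stage. It was 18217 ± 3697 (SD, n = 4) in the sums of normal libraries, 22919 ± 4259 in premalignant lesions and 27020 ± 1974 in tumor. Tumor was above normal in 4 of 4 patients. The sums held unequal numbers of libraries, and adding libraries can raise this number. In single libraries tumor was also above normal within each patient, least in patient 3 (21433 genes in normal, 21668 to 23388 in tumor). The nuclear RNA MALAT1 took on average 5.72% of the counts in normal libraries, 3.15% in premalignant lesions and 2.39% in tumor, and NEAT1 took 1.68%, 2.88% and 4.32%. These means are over libraries, and patient 1 supplied more normal libraries than any other patient. From normal to tumor MALAT1 fell in patient 1 (7.52% to 13.2%, then 3.51% and 4.82%) and patient 3 (5.57%, then 1.26% to 1.85%). It rose in patient 2 (1.52%, then 2.11% and 2.51%), and the ranges overlapped in patient 4. NEAT1 was higher in each tumor library than in any normal library of its patient. The second premalignant library of patient 2 had the fewest counts, 644064, yet 21710 detected genes.

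**Figure D1:**
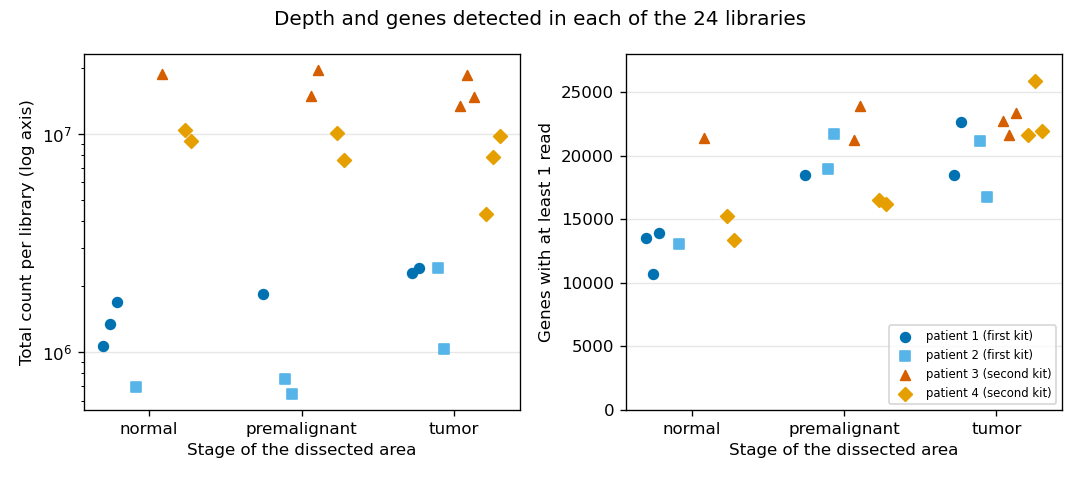
Total count on a log axis (left) and number of genes with at least 1 read (right) of each of the 24 libraries, by stage, with colour and symbol for the patient. Totals span 644064 to 2433528 in patients 1 and 2 and 4295845 to 19567595 in patients 3 and 4, and normal libraries detect 10709 to 21433 genes.

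The comparison of tumor with normal basal cells asks which genes distinguish the end of the sequence from its start. As lists, genes for motile cilia and airway secretion were lower in tumor, and genes for squamous differentiation and NRF2 targets of the oxidative stress response were higher. These lists lost their calls when the correlation between genes was estimated (adjusted p = 0.169, 0.169, 0.189 and 0.285 with an estimated correlation), and 16 of 29, 6 of 25, 3 of 31 and 3 of 23 members passed the test singly. SCGB1A1 (ENSG00000149021), the secretoglobin of club cells, fell from 6316 ± 8402 CPM (SD, n = 4) in normal to 7.12 ± 4.94 CPM in tumor. PI3 (ENSG00000124102), the protease inhibitor elafin, rose from 0.0137 ± 0.0274 to 306 ± 350 CPM. SLC7A11 (ENSG00000151012), the cystine transporter that supplies glutathione synthesis, rose from 126 ± 217 to 1446 ± 1584 CPM. Each of these changes had the same direction in 4 of 4 patients.

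The list of motile cilia genes was lower in tumor in 29 of its 29 tested members, with a median log2 fold change of −6.03 and a mean over patients of −6.27 ± 2.22 (SD, n = 4). Of these members 16 fell, and 28 fell when adjusted over the list alone. The list as a whole fell against other genes (camera adjusted p = 1.56e-57, adjusted p = 0.169 with an estimated correlation). TEKT1 (ENSG00000167858), a filament protein of the axoneme, had 118 ± 150 CPM in normal and 0 reads in tumor, at least 4386-fold lower (edgeR adjusted p = 0.000765). PIFO (ENSG00000173947) fell from 327 ± 373 to 0.717 ± 1.36 CPM, a log2 change of −10.48 (SE 1.63). DNAAF11 (ENSG00000129295), which helps assemble ciliary dynein arms, changed by −8.85 (SE 1.40). FOXJ1 (ENSG00000129654), the transcription factor of multiciliated cells, had 45.5 ± 53.6 CPM in normal and 0.685 ± 0.738 CPM in tumor, a difference of −6.10 (SE 1.91) that did not pass the test (adjusted p = 0.158). Without patient 4 the normal mean of FOXJ1 was 20.3 CPM. Among the largest falls named by size alone were CFAP54 (ENSG00000188596, log2 change −9.93, SE 1.55), MS4A8 (ENSG00000166959, log2 change −10.44, SE 1.55), CFAP276 (ENSG00000179902, log2 change −10.49, SE 1.78) and ROPN1L (ENSG00000145491, log2 change −10.18, SE 2.13). C20orf85 (ENSG00000124237) had 142 ± 274 CPM in normal and 1 read in tumor, a ratio of 16914 with a 95% interval of 3035 to 668160. Patient 4 held 97.5% of its normal CPM, and without that patient the mean was 4.81 CPM and the ratio 332 (95% interval 58.6 to 13191). WFDC6 (ENSG00000243543) had 39.8 ± 38.4 CPM in normal and 0 reads in tumor, at least 767-fold lower. It shares sequence with a read-through transcript of its neighbour, so its counts are uncertain.

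The list of secretory and mucous cell genes was lower in tumor in 20 of 25 members, with a median of −2.26, and fell against other genes (camera adjusted p = 1.09e-14, adjusted p = 0.169 with an estimated correlation). It had 6 members that fell, and 9 adjusted over the list alone. SCGB1A1 fell by 8.74 on the log2 scale (SE 1.13, adjusted p = 0.000361). SCGB3A1 (ENSG00000161055) fell from 648 ± 731 to 2.96 ± 5.45 CPM (−8.40, SE 1.49). MUC5B (ENSG00000117983), a gel-forming airway mucin, fell from 3096 ± 4444 to 49.8 ± 83.8 CPM (−6.24, SE 1.07), but it overlaps an antisense gene and the use of strand in counting is not given in the sources used here, so its value is uncertain. Immediate-early genes, transcripts induced within minutes of a stimulus, were lower in 17 of 20 members (median −1.51) and fell as a list (camera adjusted p = 1.21e-06, adjusted p = 0.169 with an estimated correlation), with 0 members called and 1 adjusted over the list alone. The normal areas, taken for their basal cells, had a median of 237 CPM over the motile cilia list, against 2.48 CPM in tumor.

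Squamous differentiation genes were higher in tumor in 29 of 31 members, with a median log2 fold change of 4.73 and a mean over patients of 4.66 ± 2.48. Of these, 3 rose, and 16 adjusted over the list alone. The list rose against other genes (camera adjusted p = 3.75e-12, adjusted p = 0.189 with an estimated correlation). PI3 had 1 read in normal, which gave a ratio of 8546 with a 95% interval of 1534 to 337570 (adjusted p = 0.0007). SPRR3 (ENSG00000163209), a precursor of the cornified envelope, rose by a log2 change of 8.06 (SE 1.74), and S100A8 (ENSG00000143546), a subunit of calprotectin, by 8.10 (SE 1.76). KRT6A (ENSG00000205420) was at 2199 ± 1885 CPM in tumor and 194 ± 194 CPM in normal (3.95, SE 1.17), a difference that did not pass the test (adjusted p = 0.130) and that is uncertain because KRT6A has near-identical paralogs. Without patient 2 its tumor mean was 1287 CPM. Mitosis genes were higher in 29 of 30 members (median 4.03) and rose as a list (camera adjusted p = 1.37e-11, adjusted p = 0.189 with an estimated correlation). None was called over all genes by edgeR, and 19 were called when adjusted over the list alone. DNA replication genes were higher in 27 of 27 members (median 3.62, camera adjusted p = 1.15e-06, adjusted p = 0.169 with an estimated correlation), and this was the list that fry called as well (adjusted p = 0.0421). MCM10 (ENSG00000065328), a replication initiation factor, was its single called member, also when adjusted over the list alone. MCM10 had 38.9 ± 43.6 CPM in tumor and 1 read in normal, a ratio of 534 with a 95% interval of 95.7 to 21116.

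Targets of NRF2, the transcription factor of the oxidative stress response, were higher in tumor in 23 of 23 members, with a median of 2.90. Of these 3 rose, and 11 adjusted over the list alone, and the list rose against other genes (camera adjusted p = 1.62e-08, adjusted p = 0.285 with an estimated correlation). SLC7A11 had a log2 change of 4.61 (SE 0.92, adjusted p = 0.00952). GPX2 (ENSG00000176153), a glutathione peroxidase of epithelia, rose from 18.4 ± 19.1 to 497 ± 340 CPM (5.38, SE 1.21). AKR1C2 (ENSG00000151632), an aldo-keto reductase with near-identical paralogs and therefore uncertain, rose from 42.6 ± 55.2 to 450 ± 267 CPM (4.23, SE 1.02). Genes of the aryl hydrocarbon and tobacco response, with 3 of 15 members, GPX2 among them, also in the NRF2 list, were higher in 11 of 12 members (median 2.86, camera adjusted p = 0.000244, adjusted p = 0.285 with an estimated correlation), with 1 called and 5 adjusted over the list alone. Genes of chromosome bands 3q26 to 3q29, a region often gained in this cancer, were higher in 25 of 29 members (median 2.18, camera adjusted p = 0.000112, adjusted p = 0.357 with an estimated correlation), with 1 called and 3 adjusted over the list alone. The called member was ATP11B (ENSG00000058063), a phospholipid flippase, at 879 ± 1101 CPM in tumor and 116 ± 121 CPM in normal (3.13, SE 0.77, adjusted p = 0.0488). Within that region, SOX2 (ENSG00000181449, log2 change 2.88, SE 1.20, adjusted p = 0.297) and TP63 (ENSG00000073282, log2 change 2.21, SE 0.82, adjusted p = 0.223) did not pass the test. The remaining large rises were P2RY1 (ENSG00000169860, log2 change 8.33, SE 2.00), an ADP receptor, ZDHHC14 (ENSG00000175048, log2 change 6.66, SE 1.46), HDAC9 (ENSG00000048052, log2 change 6.61, SE 1.56), a histone deacetylase, and PIP4P2 (ENSG00000155099), with 65.6 ± 122 CPM in tumor and 0 reads in normal, at least 157-fold higher. Patient 2 held 94.5% of the tumor CPM of PIP4P2, and without that patient the mean was 4.84 CPM and the rise at least 36.3-fold. The same patient held 86.1% of the tumor CPM of ZDHHC14. Its tumor mean was 393 CPM, and 73.1 CPM without that patient, while its log2 change was 5.43 to 8.74 with each patient left out. P2RY1 was at 130 ± 171 CPM in tumor and 1.42 ± 2.85 CPM in normal, where only patient 3 had reads. Patient 2 held 71.9% of the tumor CPM of P2RY1, and its log2 change was 6.59 to 12.2 with each patient left out. WNT5A (ENSG00000114251), a secreted Wnt ligand, rose from 11.9 ± 21.7 to 486 ± 847 CPM (5.58, SE 1.27) and was the called member of the mesenchymal transition list, which as a list did not pass the test (median 0.38, camera adjusted p = 0.833). Patient 3 held 90.3% of the tumor CPM of WNT5A, and without that patient the tumor mean was 63.1 CPM. With each patient left out in turn its log2 change was 4.54 to 6.05.

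**Figure D2:**
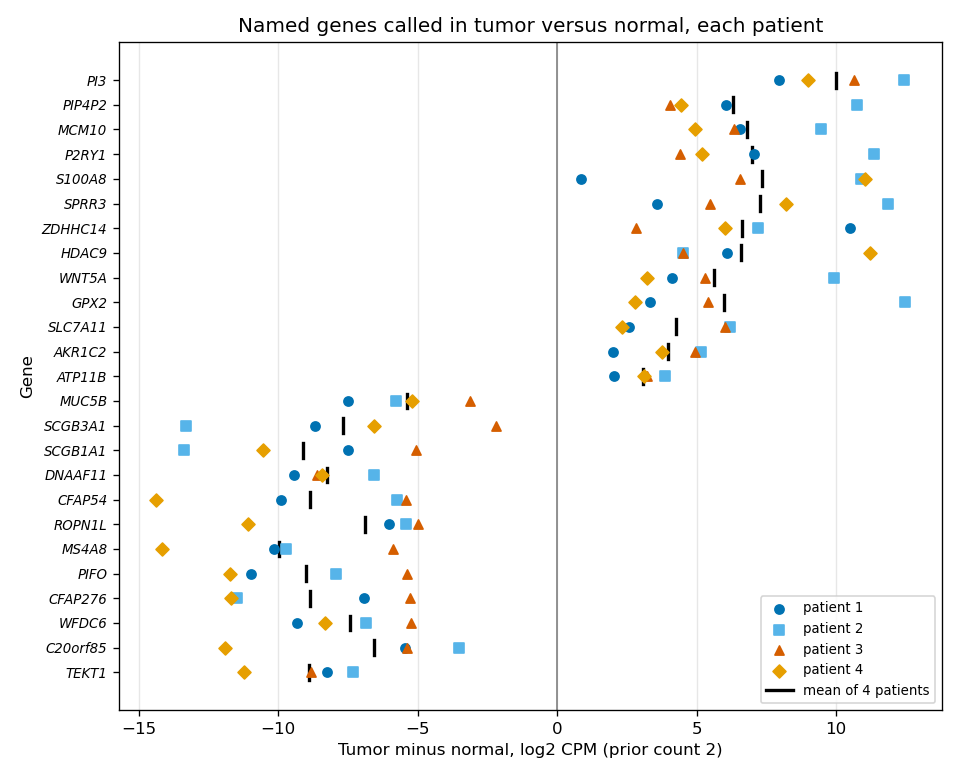
Difference in log2 CPM between tumor and normal in each of 4 patients for the 25 named genes called in that comparison, with a black bar for the mean of the patients. Each gene lies on the same side of 0 in 4 of 4 patients.

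Levels of the named genes varied widely between patients. For 21 of these 25 genes, 1 patient held over 50% of the CPM of the higher stage, summed over patients. Leaving out a patient moved the fitted fold by over 1.5 times for 20 of them, and all 25 kept their direction, with a smallest log2 change of 2.89 for ATP11B. Where a stage had 0 or 1 read, leaving out the patient with the highest level gave a drop of at least 1026-fold for TEKT1 and at least 551-fold for WFDC6, and ratios of 7543 (95% interval 1354 to 297960) for PI3 and 395 (95% interval 70.7 to 15628) for MCM10. Of the 12 named genes that fell from premalignant lesions to tumor, 10 had over 50% of their CPM in 1 patient, and the fold of all 12 moved by over 1.5 times and kept its direction. Without the highest patient the fall was at least 828-fold for TEKT1 and, with 0 tumor reads left, at least 522-fold for C2orf73.

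In all, edgeR's quasi-likelihood test called 146 of 20246 genes between tumor and normal at an adjusted p under 0.05, 22 higher and 124 lower in tumor. The share of rises depended on the fit, with 1135 higher and 774 lower for DESeq2, 519 and 255 for limma on mean log2 CPM, and 802 and 587 for the 24 libraries as samples. Without patient 1 edgeR called 38 higher, and without patient 2 it called 5. The median log2 fold change of all tested genes was 0.76, and 0.64 with relative log expression factors, so the list tests compare each list with that shift. Within the patients of the first kit 19 genes were called, of which 14 are among the 146, and within those of the second kit 99, of which 51 are. Without the patient block, which pairs the stages, 13 were called, and without patient 4 there were 82. With the number of genes detected in each sum as a covariate, which rises with the stage, 0 were called by edgeR. The median log2 change of the 22 higher genes was then 6.90 (median SE of a gene 2.56) in place of 6.60 (median SE of a gene 1.46). The camera test called 12 of 29 lists, and 13 of the 35 splits of the 8 sums, the real split included, called as many.

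The comparison of tumor with premalignant lesions asks what changes at the last step. The genes that passed were all lower in tumor, and ciliary and secretory genes were prominent among them. Motile cilia genes were lower in tumor in 28 of 29 members (median −5.07; mean over patients −4.80 ± 1.90), 9 of them fell, and 23 adjusted over the list alone (camera adjusted p = 1.36e-54, adjusted p = 0.169 with an estimated correlation). TEKT1 had 57.0 ± 69.3 CPM in premalignant lesions and 0 reads in tumor, at least 2142-fold lower. DNAH12 (ENSG00000174844), a dynein heavy chain, fell from 666 ± 643 to 1.18 ± 1.18 CPM (−8.50, SE 1.34, adjusted p = 0.00381). ZMYND10 (ENSG00000004838), needed for dynein assembly, fell from 107 ± 123 to 0.304 ± 0.452 CPM (−8.69, SE 1.63). PIFO (−8.38, SE 1.46), DNAAF11 (−7.42, SE 1.38), MS4A8 (−8.46, SE 1.45), NWD1 (ENSG00000188039, log2 change −9.49, SE 1.58) and C1orf87 (ENSG00000162598, log2 change −9.14, SE 1.81) fell as well. C2orf73 (ENSG00000177994) had 36.9 ± 18.3 CPM in premalignant lesions and 1 read in tumor, a ratio of 3882 with a 95% interval of 696 to 153400.

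Secretory genes were lower in tumor than in premalignant lesions in 23 of 25 members (median −2.08), and 5 fell. Adjusted over the list alone 11 fell and 1 rose (camera adjusted p = 2.18e-13, adjusted p = 0.169 with an estimated correlation). SCGB1A1 fell from 1706 ± 2228 to 7.12 ± 4.94 CPM (−6.88, SE 1.06, adjusted p = 0.00381), MUC5B from 482 ± 506 to 49.8 ± 83.8 CPM (−5.83, SE 1.14), and BPIFB1 (ENSG00000125999), a secreted airway protein, from 3135 ± 5877 to 135 ± 236 CPM (−4.66, SE 0.94). Patient 4 held 95.3% of the premalignant CPM of BPIFB1, and without that patient the premalignant mean was 197 CPM. With each patient left out in turn its log2 change was −5.24 to −3.56. In tumor 8 lists were higher, with 0 members called by edgeR, and they included NRF2 targets (median 2.02, camera adjusted p = 4.69e-07, adjusted p = 0.357 with an estimated correlation; 6 adjusted over the list alone), 3q genes (median 1.26, camera adjusted p = 4.67e-05, adjusted p = 0.357 with an estimated correlation) and squamous differentiation (median 1.46, camera adjusted p = 6.89e-05, adjusted p = 0.553 with an estimated correlation; 3 adjusted over the list alone). Immediate-early genes were lower (median −1.12, camera adjusted p = 1.24e-06, adjusted p = 0.169 with an estimated correlation).

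edgeR called 49 genes between tumor and premalignant lesions, 0 higher and 49 lower in tumor, with 1160 genes at an unadjusted p under 0.05 in either direction. DESeq2 called 196 higher, and limma on mean log2 CPM called 7. The median log2 fold change of all genes was 0.33, and the sums of tumor also had more genes detected than those of premalignant lesions. Within patients 1 and 2 edgeR called 0 genes and within patients 3 and 4 it called 76. It called 114, 32 and 11 genes without patient 1, 3 and 4, and 0 without the patient block, by which the stages are paired. The camera test called 11 of 29 lists, and 11 of the 35 splits called as many.

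Premalignant lesions were compared with normal basal cells to ask what changes first. Genes of cell division and of squamous differentiation were higher in premalignant lesions as lists, and edgeR called no single gene where DESeq2 called 360. With an estimated correlation the list calls were lost (adjusted p = 0.189 for mitosis, 0.189 for DNA replication and 0.285 for squamous differentiation). Mitosis genes were higher in 27 of 30 members and in 4 of 4 patients, with a median log2 fold change of 2.84 and a mean over patients of 3.10 ± 1.84 (camera adjusted p = 5.76e-12, adjusted p = 0.189 with an estimated correlation), with 0 called also when adjusted over the list alone. MKI67 (ENSG00000148773), a marker of cycling cells, was at 481 ± 705 CPM in premalignant lesions and 122 ± 201 CPM in normal (2.18, SE 1.23, adjusted p = 0.910) and higher in 3 of 4 patients. Patient 1 held 78.6% of the premalignant CPM of MKI67. Without that patient the premalignant mean was 137 CPM, where the normal values of the other patients were 0, 56.6 and 9.77 CPM. DNA replication genes were higher in 23 of 27 members and in 3 of 4 patients (median 2.32, camera adjusted p = 3.18e-05, adjusted p = 0.189 with an estimated correlation; 1 adjusted over the list alone). Squamous differentiation genes were higher in 27 of 31 members and in 4 of 4 patients (median 2.53, camera adjusted p = 2.57e-08, adjusted p = 0.285 with an estimated correlation; 1 adjusted over the list alone). KRT6A was at 674 ± 491 CPM against 194 ± 194 CPM (2.33, SE 1.13, adjusted p = 0.875) and higher in 3 of 4 patients. Its premalignant mean was 436 CPM without patient 1, where the normal values of the other patients were 62.1, 405 and 0.142 CPM.

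Motile cilia genes were lower in premalignant lesions than in normal in 27 of 29 members but in 3 of 4 patients (median −1.24, camera adjusted p = 6.02e-08, adjusted p = 0.455 with an estimated correlation), and secretory genes in 16 of 25 members and in 2 of 4 patients (median −0.40, camera adjusted p = 0.0189, adjusted p = 0.605 with an estimated correlation). SCGB1A1 was at 1706 ± 2228 CPM in premalignant lesions and 6316 ± 8402 CPM in normal (−1.87, SE 0.84, adjusted p = 0.860), lower in 3 of 4 patients. Without patient 4 its means were 609 CPM in premalignant lesions and 2230 CPM in normal. Genes of the aryl hydrocarbon and tobacco response (median 1.89, camera adjusted p = 0.00406, adjusted p = 0.397 with an estimated correlation), NRF2 targets (median 1.21, camera adjusted p = 0.0179, adjusted p = 0.669 with an estimated correlation) and glycolysis and hypoxia genes (median 0.82, or 0.64 with genes at 0 reads set to their bound, camera adjusted p = 0.0357, adjusted p = 0.718 with an estimated correlation) were higher, the last 2 in 3 of 4 patients, and MHC class II genes, which present antigen to helper T cells, were lower as a list but in 2 of 4 patients, with a mean over patients of −0.04 ± 1.82 (median −1.08, camera adjusted p = 0.0303, adjusted p = 0.669 with an estimated correlation). The basal cell and hemidesmosome list did not pass the test (median −0.32, camera adjusted p = 0.833).

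edgeR called 0 of 20246 genes between premalignant lesions and normal, with 1145 at an unadjusted p under 0.05 and a smallest adjusted p of 0.750. DESeq2 called 273 higher and 87 lower, the fits of limma called 0, and edgeR called 2 without patient 1 and 2 without patient 3. The median log2 fold change of all genes was 0.37, and the sums of premalignant lesions had more genes detected than those of normal in 3 of 4 patients. The camera test called 10 of 29 lists, and 6 of the 35 splits called as many.

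**Figure D3:**
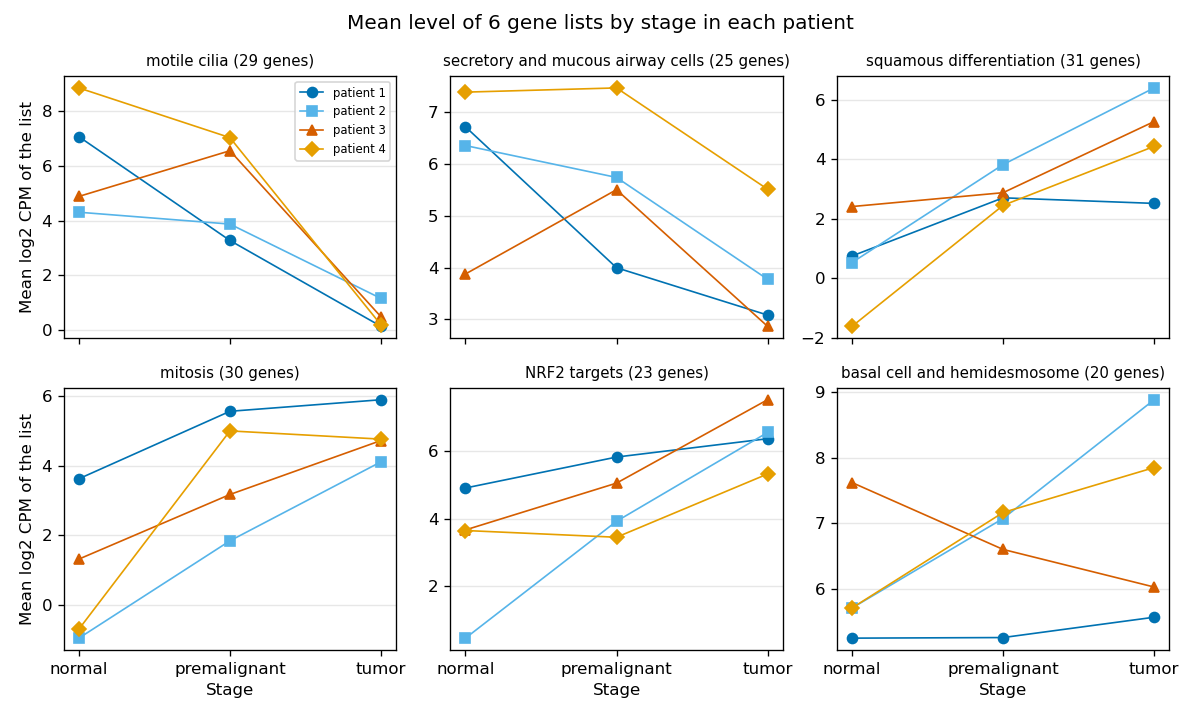
Mean log2 CPM of 6 gene lists by stage, with a line for each of 4 patients. Motile cilia genes are lowest in tumor in 4 of 4 patients, and mitosis genes are lowest in normal in 4 of 4 patients.

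Some lists of markers of other cell types passed the camera test with the preset correlation, and none passed with an estimated correlation. Myeloid cell markers were higher in tumor than in normal in 19 of 19 members (median 3.54, camera adjusted p = 0.000258, adjusted p = 0.397 with an estimated correlation; 4 adjusted over the list alone), in tumor than in premalignant lesions, where 2 of 4 patients were higher (mean over patients 1.64 ± 2.37, median 2.16, camera adjusted p = 0.0179, adjusted p = 0.553 with an estimated correlation) and in premalignant lesions than in normal (median 1.69, camera adjusted p = 0.0179, adjusted p = 0.605 with an estimated correlation). Fibroblast and extracellular matrix genes were higher in 3 of 4 patients in tumor than in normal (median 3.34, camera adjusted p = 0.0165, adjusted p = 0.723 with an estimated correlation; 2 adjusted over the list alone) and in 3 of 4 patients than in premalignant lesions (median 2.47, camera adjusted p = 0.000159, adjusted p = 0.605 with an estimated correlation). Alveolar markers were higher in tumor than in premalignant lesions in 4 of 4 patients (median 4.23, camera adjusted p = 4.67e-05, adjusted p = 0.233 with an estimated correlation; 6 adjusted over the list alone). They did not pass between tumor and normal (median 4.27, camera adjusted p = 0.130) or between premalignant lesions and normal (median −0.71, camera adjusted p = 0.113). No member of these lists was called over all genes by edgeR. The lists of endothelial, smooth muscle, T and NK cell, B and plasma cell and erythrocyte markers did not pass the test between tumor and normal, with medians of 4.49, 3.28, −0.13, −1.35 and −4.60 and camera adjusted p of 0.131, 0.17, 0.412, 0.117 and 0.0622.

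The series title speaks of stepwise carcinogenesis, so the genes were also asked whether they moved at each step. The number of genes called in the same direction at both steps was 0 with edgeR and 4 with DESeq2. With edgeR it could only be 0, because 0 genes were called at the first step, so it does not show that no gene moved at both. In the test of premalignant lesions against the midpoint of normal and tumor, edgeR called 0 genes, with 780 at an unadjusted p under 0.05, and DESeq2 called 110. Without patient 1 edgeR called 7. The genes lower in tumor than in premalignant lesions were largely lower than in normal as well. Of the 49 genes, 47 were among the 124 that fell against normal, where independent lists would share 0.300. Both comparisons use the same tumor libraries. Between patients who share no library, 7 genes were among both the 66 that fell against premalignant lesions in patients 3 and 4 and the 16 that fell against normal in patients 1 and 2, where independent lists would share 0.071.

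The changes from normal to premalignant and from normal to tumor were correlated across genes. In the same patients r was 0.649 over 20246 genes, but unchanged genes simulated against the same normal libraries gave 0.506. The covariance was 2.17 against a simulated 0.996, a difference of 1.18. When premalignant lesions and tumor came from different patients, no library was shared and the simulated r was near 0 (SD 0.00592). The observed r was then 0.161 (Spearman's rho 0.141) with premalignant lesions of patients 1 and 2 and tumor of patients 3 and 4, and 0.0531 (rho 0.050) the other way round. The 4 other divisions of the patients gave r of 0.0377 to 0.147. These correlations are across genes, and genes are not independent replicates.

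The library kit differed between patients 1 and 2 and patients 3 and 4, and the stage differences of some genes differed with it. edgeR's interaction test called 12 genes for premalignant lesions against normal and 12 for tumor against normal. Dividing the patients otherwise, 1 and 4 against 2 and 3, gave 0 and 17, so the 12 for tumor against normal do not stand out. MUC5B was lower in premalignant lesions than in normal by a mean log2 difference of −4.01 in patients 1 and 2 and higher by 1.89 in patients 3 and 4 (interaction 6.20, adjusted p = 0.0325), and its overlapping antisense gene MUC5B-AS1 (ENSG00000255177) differed likewise (−5.23 and 5.90). SCGB3A2 (ENSG00000164265), another secretoglobin, differed by 1.68 and −7.11, and BPIFA1 (ENSG00000198183) differed by −8.52 and 4.07 between tumor and normal. MUC5B-AS1, SCGB3A2 and BPIFA1 were chosen after their values were seen. The kit and the patients using it cannot be separated, and leaving out any patient left 0 to 4 such genes.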

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

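The count of other splits of the patients was chosen after the result was seen. Values of 239 groups were searched for a patient or library far from the rest of its group, measured as the gap to the nearest value divided by the range of the group. Of these, 22 stood out, 12 high and 10 low, or about 1 in 11, and 8 were in patient 2. Chance gives about 1 in 20 for continuous values, but in 7 of the 22 the other patients tied at 0 reads, where that rate does not apply, so no excess over chance is read from the number.

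In some genes 1 patient alone had reads and the rest of the group had 0. The share was 1 for C2orf73, C20orf85 and CFAP276 in tumor, for PI3, MCM10 and P2RY1 in normal, and for CDKN2A in normal, where that patient had 4.86 log2 CPM. Among genes lower in tumor, 1 patient was low for NWD1 in normal (0.874) and in tumor (0.841), for C1orf87 in premalignant lesions (0.839) and for SCGB1A1 in tumor (0.865), and 1 was high for ROPN1L in normal (0.853). Among squamous genes, 1 patient was low for S100A8 in tumor (0.837) and for SPRR3 in premalignant lesions (0.846), which had 0 reads there. SOX2 was low in 1 tumor (0.835), at 5.78 log2 CPM where the others had 8.30 to 8.80, and PIK3CA was low in 1 normal sum (0.919).

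Gene lists stood out in single patients as well. MHC class I genes (0.851) and T and NK cell markers (0.873) were high in tumor of 1 patient each. Mesenchymal transition genes were high (0.851) and immediate-early genes low (0.872) in premalignant lesions of 1 patient each. Genes of the aryl hydrocarbon and tobacco response were low in normal of 1 patient (0.856). Among the 7 normal libraries, the only one of patient 3 detected 21433 genes, where the others detected 10709 to 15297 (0.572).

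Stage differences that differed between the library kits by an interaction test numbered 12 for premalignant lesions against normal and 12 for tumor against normal. MUC5B had an interaction of 6.195 on the log2 scale for premalignant lesions against normal. Of the 3 splits of the 4 patients into equal groups, 1 gave as many as the 24 of both comparisons, the kit's own, and the highest other gave 17. All of these 17 were for tumor against normal, where the kit's own split gave 12 and so does not stand out. For premalignant lesions against normal the other splits gave 0. With 3 splits the share cannot fall under 0.05.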

How the results depend on the processing

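The fit without the second premalignant library of patient 2 and the fit with the number of genes detected as a covariate were chosen after the result was seen. No called named gene and no called list reversed its direction under any alternative. Between tumor and normal, against 146 genes called (22 higher), DESeq2 called 1909 (1135 higher), no filter on low counts 308 (80 higher), no replicate block, that is without pairing by patient, 13 (1 higher), the 24 libraries as samples 1389 (802 higher), limma on mean log2 CPM 774 (519 higher), log2(RPKM + 1) 17 (14 higher), log2(RPKM + 0.1) 938 (789 higher), log2(RPKM + 1) with an RPKM filter 305 (250 higher), patients 1 and 2 alone 19, and the covariate 0. Leaving out each patient gave 82 to 147. Between tumor and premalignant lesions, against 49 (0 higher), the same settings gave 600 (196 higher), 139 (15 higher), 0 with no replicate block, 395 (61 higher), 93 (7 higher), 0, 14 (6 higher), 5 (4 higher), 0 in patients 1 and 2 alone, 76 in patients 3 and 4 alone and 28 with the covariate. Upper-quartile factors gave 27, and leaving out each patient 11 to 114. Between premalignant lesions and normal, against 0, DESeq2 called 360, no filter 2, the fit of these stages alone 2 and leaving out each patient 0 to 2. Against the midpoint, where 0 were called, DESeq2 called 110, no filter 14, the 24 libraries 18, patients 1 and 2 alone 1, patients 3 and 4 alone 3 and leaving out each patient 0 to 7. Genes called at both steps numbered 0, and 4 with DESeq2, but with 0 calls at the first step the main count could only be 0. For library kit by stage, against 24 in both comparisons together, DESeq2 called 576, relative log expression factors 7 and leaving out each patient 0 to 4. Of 87 list tests, 33 were called with the preset correlation, 0 with an estimated correlation and 1 with fry. Without the block 35 were called, and the block changed no other call by over 1.5 times. DESeq2 called 146 of the same 146 genes, and after thinning 135 of them were called. For the covariate, the standard errors of the genes called between tumor and normal grew while their folds stayed. For the other comparisons and settings the cause was not tested. The remaining settings kept each count within 1.5 times. Each called named gene kept its direction in every setting that tested it, and 8 to 20 of its 19 to 21 settings called it. Of 777 list results under alternatives, 646 stayed on their side of the threshold, 90 lost it and 41 gained it. Fixed genes that were not called changed direction in 103 results, among them CDKN2A between tumor and premalignant lesions and NOTCH1 between premalignant lesions and normal under upper-quartile factors. Libraries thinned to equal totals gave 187 genes between tumor and normal and 63 between tumor and premalignant lesions. The sums of thinned libraries remained unequal, so this does not decide whether depth limits these counts. On simulated counts the edgeR test called 2.38% of 4-fold and 29.5% of 64-fold changes between tumor and normal.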

Other observations

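The splits for counts of genes, the reading of the thinned fit (the fit itself was planned), the test of ciliary and secretory levels and the fit with the covariate were chosen after the result was seen.

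Of the 18 fixed genes, SCGB1A1 alone passed the edgeR test between tumor and normal, and the genes often altered in squamous lung cancer did not. TP63, the transcription factor of basal and squamous cells, was at 3160 ± 4062 CPM (SD, n = 4) in tumor and 486 ± 157 CPM in normal and higher in 4 of 4 patients. Patient 2 held 72.6% of its tumor CPM, and without that patient the tumor mean was 1155 CPM. KRT5 (ENSG00000186081) differed by a log2 change of 0.88 (SE 0.84), MYC (ENSG00000136997) by 0.15 (SE 1.03), EGFR (ENSG00000146648) by −0.05 (SE 0.79), CCND1 (ENSG00000110092) by 0.99 (SE 1.21) and PIK3CA (ENSG00000121879) by 1.36 (SE 1.08). The mean of CCND1 went against its fitted change, with 207 ± 92.8 CPM in tumor and 353 ± 635 CPM in normal. Patient 3 held 92.5% of its normal CPM, and 3 of 4 patients were higher in tumor. NFE2L2 (ENSG00000116044), which encodes NRF2, differed by 1.62 (SE 0.80, adjusted p = 0.406), and CDKN2A (ENSG00000147889) by 5.27 (SE 2.21, adjusted p = 0.297). MKI67 differed by 3.76 (SE 1.29, adjusted p = 0.185) and was higher in 4 of 4 patients. E2F1 (ENSG00000101412) had 0 reads in normal and was at least 26.1-fold higher in tumor (adjusted p = 0.222). FGFR1 (ENSG00000077782), NOTCH1 (ENSG00000148400) and CD274 (ENSG00000120217) differed by −0.53 (SE 1.49), −0.29 (SE 1.80) and 0.92 (SE 1.98). NOTCH1 had means against the sign of its fitted change, 9.06 ± 7.93 CPM in tumor and 7.89 ± 9.45 CPM in normal, and 2 of 4 patients were higher.

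Glycolysis and hypoxia genes were higher in tumor than in normal (median 1.78, camera adjusted p = 0.000502, adjusted p = 0.578 with an estimated correlation; 0 called and 1 adjusted over the list alone) and than in premalignant lesions (median 0.85, camera adjusted p = 0.0239, adjusted p = 0.718 with an estimated correlation). Ribosomal protein genes were higher in tumor than in premalignant lesions in 3 of 4 patients (median 0.77, camera adjusted p = 0.0370, adjusted p = 0.771 with an estimated correlation). The lists of basal cell and hemidesmosome genes, oxidative phosphorylation, MHC class I, MHC class II, interferon-stimulated genes, MYC-associated growth genes, matrix proteases, p53 targets and the Notch pathway did not pass the test between tumor and normal. Their medians were 0.66, 0.69, 0.62, −0.00419, 2.11, 0.59, 1.03, 0.53 and −0.15, and their camera adjusted p were 0.631, 0.328, 0.564, 0.17, 0.0633, 0.631, 0.473, 0.95 and 0.825. The direction of the camera test was unlike the sign of the median or mean in 14 of 87 tests, 0 of them called.

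The genes called between tumor and normal exceeded what other splits of the same 8 sums gave. The real split called 146 and the highest of the others 2, so that 1 of 35 splits reached the real count. For tumor against premalignant lesions the real split called 49 and the highest other 7, again 1 of 35. A share of 1 in 35 is the smallest that these splits can give. The sums are also paired by patient, which most of the splits ignore, so chance is not excluded. For premalignant lesions against normal the real split called 0, which 35 of 35 splits reached, and the highest other called 1. Only 8 splits part all 4 pairs as the real one does, and the others leave sums of a patient on the same side. Of those 8, the highest other called 0 in each comparison, and 8 are too few for a share under 0.05. For the number of gene lists called, chance cannot be excluded. Premalignant lesions against normal called 10 lists (6 of 35 splits, highest other 15), tumor against premalignant lesions 11 (11 of 35, highest other 16) and tumor against normal 12 (13 of 35, highest other 17). List by list, motile cilia and secretory genes had a smaller p than in any other split in both tumor comparisons. In tumor against normal, the smallest other camera p was 1.35e-48 for motile cilia (real split 1.80e-59) and 1.31e-14 for secretory genes (real 3.77e-16). In tumor against premalignant lesions it was 3.23e-46 (real 3.13e-56) and 1.40e-11 (real 1.00e-14). The size of these p-values therefore does not measure how unusual the real split is. In premalignant lesions against normal 8 and 12 of 35 splits reached the p of motile cilia and secretory genes. Mitosis genes were reached by 3 of 35 splits in tumor against normal and by 2 of 35 in premalignant lesions against normal, and squamous differentiation genes by 3 and 2. In tumor against premalignant lesions 7 of 35 reached squamous differentiation genes. Of the called lists, fibroblast and extracellular matrix genes in tumor against normal were reached most often, by 15 of 35.

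A hypothesis for the 22 genes higher in tumor than in normal is a technical one, that normal libraries were shallower or less complex. Single normal libraries were shallower than each tumor library of their patient in patients 1 and 2 only. In patient 3 the normal library held 18892997 counts and tumor libraries 13399648 to 18508865. The ranges overlapped in patient 4, with 9259028 and 10408882 in normal and 4295845 to 9789138 in tumor. After each library was thinned to the same total, 20 of the 22 were still called and 21 kept at least a 2-fold rise. This argues against the depth of single libraries as the whole cause. The tested sums still held 7 normal and 10 tumor libraries in all, so unequal depth of the sums was not removed. With the number of genes detected as a covariate, 0 of the 22 were called. Their median log2 change was 6.60 (median SE of a gene 1.46) before and 6.90 (median SE of a gene 2.56) after, and the call ended because the covariate moves with the stage and widens the error. Fewer genes detected in normal areas and a difference of the tumor cells cannot be told apart here, since both follow the stage.

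The falls of ciliary and secretory genes may reflect ciliated and secretory cells within the dissected normal areas, although the areas were taken for basal cells. The median level over the 29 motile cilia genes was 236.9 CPM in normal and 2.483 CPM in tumor, and SCGB1A1 and MUC5B stood at 6316 and 3096 CPM in normal. The falls require normal to exceed tumor but do not set the level in normal. These levels are means over patients and were uneven. In normal, MUC5B was at 1.095 CPM in patient 3, and SCGB1A1 ranged from 264 CPM in patient 3 to 18570 CPM in patient 4. The mean log2 CPM of the motile cilia list in normal was 7.07, 4.31, 4.88 and 8.85 in patients 1 to 4. Ciliary RNA was thus present in the normal areas of each patient, and the amount of secretory RNA differed widely between patients. The levels do not show which cells carried this RNA, so they do not decide for or against such cells. Of the 30 genes on the motile cilia list, 0 are on another list. A loss of these transcripts by the cells themselves was not tested, and it cannot be told apart from other cells in the normal areas.

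The falls could also belong to the kit of patients 1 and 2 alone. Of the 100 genes with the smallest p for a fall in those patients, 86% were lower in patients 3 and 4 relative to all genes, with a median log2 change of −5.04, which argues against it. Whether the falls rest on patients 3 and 4 alone was not tested in this way. Between tumor and normal, 16 genes were called lower within patients 1 and 2 and 87 within patients 3 and 4. Between tumor and premalignant lesions the numbers were 0 and 70. As a description, genes called lower without a given patient had that direction in the patient left out in 94.1%, 71.1%, 89.2% and 88.9% of cases for patients 1 to 4, where 43.0%, 26.9%, 40.5% and 36.7% of all genes did. Genes called higher did so in 33 of 38, 4 of 5, 19 of 21 and 11 of 18 cases, where 53.3%, 64.9%, 59.5% and 58.7% of all genes did. In patient 4 the share of 61.1% was close to that of all genes, while the median log2 difference of these genes was 2.89 against 0.71 for all genes.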
